A study of Homo sapiens with 10 samples.

How the data were processed

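RNA was measured in 10 libraries from human cells. Of these, 8 came from HL-60, an established promyelocytic leukaemia line, in 4 groups of 2: wildtype and mutant cells, each untreated or given phorbol myristate acetate (PMA), a phorbol ester that activates protein kinase C. The mutant line had been targeted by CRISPR/Cas9 at the EGR1 binding site of FIRE, an enhancer inside the CSF1R gene, per the series record. The other 2 libraries came from primary monocytes and primary macrophages of healthy donors, 1 library each.

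Per the labels' protocols, total RNA was extracted with a column kit and kept where its integrity number was above 8. The HL-60 libraries were 3′ mRNA libraries made with a QuantSeq kit, which reads the end of polyadenylated RNA. The monocyte and macrophage libraries were strand-marking total RNA libraries made after ribosomal RNA depletion. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, FastQC, Trim Galore, STAR, SAMtools, RSEM, featureCounts and DESeq2, on the human build hg19; versions other than that of bcl2fastq are not given in the sources used here, except where a file header gives one. Per the file headers, the authors counted reads with featureCounts 1.5.1 over whole gene bodies, introns included, from alignments filtered at a mapping quality of 10. The HL-60 counts used Ensembl release 87 on GRCh37 and strand setting 1, and the monocyte and macrophage counts used GENCODE release 24 lifted to GRCh37 and strand setting 2, per the file headers. The deposited values are raw read counts per gene, 1 library per file, with no normalization by the authors. No mitochondrial gene had a read in the HL-60 libraries. Gene symbols and types came from a GENCODE release on GRCh38 by Ensembl identifier, and covered 99.22% of the counts in the HL-60 libraries and 99.04% in the other 2. Coordinates are those of the count files, on GRCh37.

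Total counts per HL-60 library ran from 4960617 to 8633974. The monocyte library held 14460218 counts and the macrophage library 13421964. A count of 0 allows up to 3 counts, which is 0.347 to 0.605 CPM (counts scaled to equal library totals) in the HL-60 libraries, 0.207 CPM in the monocyte library and 0.224 CPM in the macrophage library. Intervals on single libraries and on ratios of counts are exact 95% intervals (Poisson for a level, Clopper-Pearson for a ratio). The libraries carry no molecular identifiers, so intervals and floors cover counting error only. The labels do not state that replicates came from separate cultures, so the p-values measure only the spread between these samples.

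The 8 HL-60 libraries were tested together with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM normalization, filterByExpr by group, a quasi-likelihood fit of 4 group means, and Benjamini-Hochberg adjustment over the 13744 genes kept. A gene was called at an adjusted p under 0.05. Of 5 contrasts, 2 set PMA against untreated cells within a line, 2 set mutant against wildtype cells within a treatment, and 1 tested the difference between both PMA responses (the interaction). The 4 groups of 2 shared 1 estimate of the spread with 4 residual degrees of freedom; the common biological coefficient of variation was 37.4%. Normalized levels are TMM-scaled CPM, given as mean ± SD over n = 2 libraries. Errors of log2 fold changes are approximate standard errors (SE). They were computed as the absolute log2 change over the square root of the F statistic, and not fitted directly. A fold against a group with no read was computed against 3 counts over the group and is a lower bound. With 1 to 3 reads in a group, a ratio of pooled counts with its 95% interval is given instead.

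Same-numbered libraries were checked for shared deviations from their group means. The difference between replicate 1 and replicate 2 correlated between groups in all 6 pairs of groups, with r from 0.258 to 0.541 across 8458 genes. Per the file headers, every replicate 1 library was counted from 1 run folder and every replicate 2 library from another, so the replicate number goes with the run, and a shared run, culture day or harvest cannot be told apart. The fit without the replicate number had been chosen before the data were examined and stays the main one. The fit with replicate as a block, whose coefficient of variation was 26.7%, is given beside a result where it changes the call or moves a count of calls by over 1.5 times.

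The gene lists were fixed before the data were examined and tested with camera (preset inter-gene correlation 0.01), adjusted by Benjamini-Hochberg over the lists of a contrast. There were 30: regulators of CSF1R transcription, immediate early and EGR family, cell cycle, ribosome biogenesis and MYC targets, inflammatory cytokines and chemokines, NF-kappaB targets, interferon response, MHC class II, phagocyte NADPH oxidase and receptors, lysosome, adhesion and cytoskeleton, cholesterol biosynthesis, lipid efflux and LXR, p53 and growth arrest, protein kinase C family, cohesin and chromatin architecture, CSF1R locus neighbours, CSF1R ligands and downstream signalling, oxidative phosphorylation, glycolysis and hypoxia, dissociation and heat stress, and markers of monocytes, macrophages, neutrophil granules and promyelocytes, T and NK cells, B cells, platelets and megakaryocytes, erythroid cells, mature neutrophils and dendritic cells. The tests, contrasts, lists and alternatives were also fixed before the data were examined. In HL-60 cells 28 lists had at least 3 tested members, and 2 (MHC class II and dendritic cell markers) had fewer and were not tested. From the lists, 7 symbols were not matched in the HL-60 counts and 3 in the other counts.

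Named genes followed a rule fixed before the data were examined: CSF1R and EGR1; in each contrast the 10 called genes with the largest change in each direction among those with a mean of at least 10 CPM whose libraries did not overlap between the groups; and up to 4 called members of each list that passed its test, smallest adjusted p first. Some of these are given in the text. Pseudogenes, unnamed clones, XIST and Y-linked genes were left out. Mutant against wildtype contrasts had no calls, so the same rule was applied there to the blocked fit, a step chosen after the result was seen. Monocyte and macrophage libraries were compared by the log2 ratio of CPM with 1 CPM added to each, without a test, since each group had 1 library. For each list, the median log2 ratio was placed among 10000 random lists of the same size matched on mean CPM. Named genes there were the 15 with the largest ratio in each direction at a mean of at least 20 CPM, and list members.

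Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no low-count filter, a filter at a mean of 1 CPM, only the groups compared, the replicate block, a minimum log2 change of 1, an adjusted p under 0.01, each library left out in turn, camera with an estimated correlation, and fry. Protein-coding genes only, genes with a mean of at least 10 CPM for the relation of both responses, and genes above their length expectation in the primary cells were added after seeing the data. The edgeR procedure was tested on simulated data with the mean levels, library sizes and trended spread of these libraries and 200 changed genes. It recovered 53 of 95 genes with a 4-fold change and 6 of 96 with a 2-fold change in the contrast of PMA within the wildtype, where 3.3% of calls were unchanged genes. For the interaction it recovered 12 of 99 genes with a 4-fold change. The simulated groups shared their mean levels, held no replicate or run effect, and had far fewer changed genes than the PMA contrasts called. These rates therefore need not hold for the data. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.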

Results

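Gene expression was measured in HL-60 cells and in primary human monocytes and macrophages. The HL-60 part held wildtype and enhancer mutant cells, untreated or after PMA, which drives these cells towards monocytes, with 2 libraries per group. Untreated libraries held 6849592 and 6558639 counts (wildtype) and 8633974 and 5632550 (mutant), and PMA libraries 7217663 and 6445046 (wildtype) and 6899314 and 4960617 (mutant). In HL-60 cells, the first principal component, with 64.6% of the variance, separated PMA from untreated libraries. The second, with 15.4%, placed replicate 1 above replicate 2 in each of the 4 groups.

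CSF1R, the receptor for macrophage colony-stimulating factor whose enhancer was edited, rose with PMA in wildtype cells. The gene (ENSG00000182578, chromosome 5, 149432854 to 149492935, GRCh37) went from 0.165 ± 0.234 to 14.9 ± 4.08 CPM (SD, n = 2), a log2 change of 6.39 ± 1.51 (SE, adjusted p = 0.0215, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). By pooled counts, 199 reads after PMA against 2 before, the ratio was 97.6 (95% interval 26.7 to 812), or 49.9 (13.6 to 415) without replicate 2 of the untreated wildtype and at least 31.8-fold without its replicate 1. In mutant cells CSF1R stood at 1.51 ± 2.13 CPM before and 4.11 ± 3.17 CPM after PMA, a log2 difference of 1.34 ± 1.13 that did not pass (adjusted p = 0.495). After PMA the mutant had fewer CSF1R reads than the wildtype in both runs, with ratios of 0.146 (0.0726 to 0.268) and 0.379 (0.249 to 0.564), and 0.261 (0.184 to 0.362) over both. Across replicates that difference of −1.87 ± 1.09 on the log2 scale did not pass (adjusted p = 0.758). Before PMA the counts were 2 and 0 in wildtype libraries and 28 and 0 in mutant libraries, so the mutant level rested on replicate 1. The 2 PMA responses differed by −5.05 ± 1.9, which did not pass (adjusted p = 1, edgeR).

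Replicate 1 of the untreated mutant decided several of the CSF1R values. Without that library the mutant response to PMA passed (adjusted p = 0.0401, edgeR). The other untreated mutant library had no CSF1R read, so by counts that response was at least 7.12-fold, and neither the untreated difference between lines (0 reads against 2) nor the difference between both responses had a measurable size. The same library had reads in 22270 genes, against 17557 to 19631 in the other HL-60 libraries, and 407 genes with at least 10 reads that had at most 2 in each of the other 7. The wildtype call was lost without replicate 2 of the untreated wildtype (5.40, adjusted p = 0.0785, edgeR). With no low-count filter the difference between responses passed (−5.01, adjusted p = 0.0364, edgeR).

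**Figure D1:**
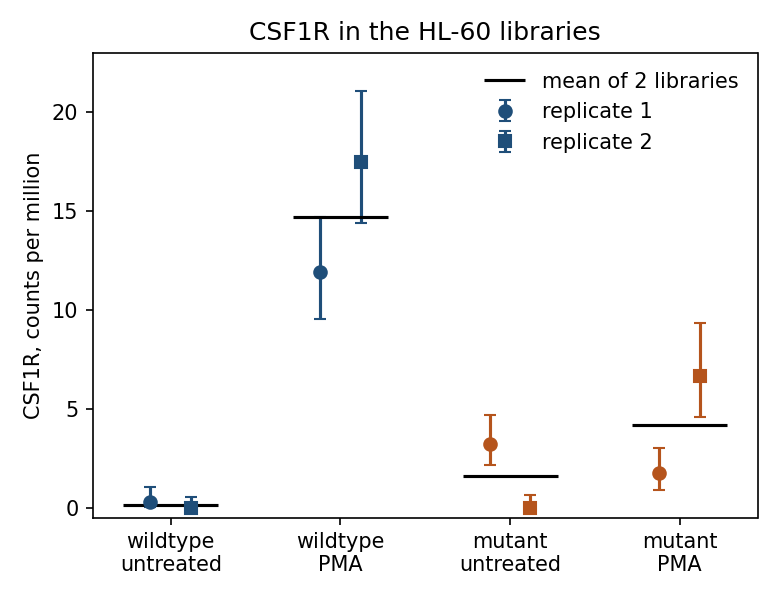
CSF1R in each HL-60 library, in CPM of the library total (vertical axis), by group. Circles are replicate 1 and squares replicate 2, bars are exact 95% counting intervals and lines the mean of 2 libraries. Wildtype PMA libraries stood at 11.9 and 17.5, mutant PMA libraries at 1.74 and 6.65.

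EGR1, the immediate early transcription factor whose binding site was edited, rose with PMA in wildtype cells. The gene (ENSG00000120738, chromosome 5, 137801179 to 137805004) went from 246 ± 149 to 854 ± 119 CPM, a log2 change of 1.80 ± 0.51 (adjusted p = 0.0454, edgeR). The mutant went from 223 ± 141 to 725 ± 173 CPM, with a log2 difference of 1.70 ± 0.51 just over the threshold (adjusted p = 0.0527, edgeR) and under it with the replicate block (adjusted p = 0.000599). It also passed without either untreated wildtype library (0.0215 and 0.0121), either wildtype PMA library (0.0433 and 0.0233), replicate 1 of the untreated mutant (0.0175) or replicate 2 of mutant PMA (0.0308), all by edgeR. Between lines EGR1 differed by −0.14 ± 0.5 untreated and −0.23 ± 0.5 after PMA, and neither passed (adjusted p = 1 and 0.961, edgeR). The wildtype call was lost without replicate 2 of the untreated wildtype (1.26, adjusted p = 0.223), without replicate 1 of the wildtype PMA group (1.65, adjusted p = 0.141) and without its replicate 2 (1.91, adjusted p = 0.0504), all by edgeR.

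The wildtype comparison asked what PMA changes in HL-60 cells. MMP9, a secreted gelatinase, went from 0.165 ± 0.234 to 429 ± 85 CPM (ratio of counts 2810, 779 to 23200). MB, which encodes myoglobin, had a ratio of 2570 (461 to 102000), CDKN1A, the p21 inhibitor of cyclin-dependent kinases, 1440 (259 to 57100), and IL1RN, the antagonist of the interleukin 1 receptor, 1210 (217 to 47800). Reads of IL7R, the interleukin 7 receptor, were at least 295-fold higher, those of XIRP1, an actin-binding protein of muscle, at least 127-fold, and those of ZNF365 at least 93.2-fold. The antisense RNA ROR1-AS1 had a ratio of 1340 (241 to 53100), and PHLDA1 rose by 8.99 ± 0.54 on the log2 scale, to 453 ± 45.4 CPM. KCNN4, a calcium-activated potassium channel, was at least 28.8-fold higher. These sizes rest on the depth of both untreated libraries. Without replicate 2 of the untreated wildtype the ratios were 1440 for MMP9, 1310 for MB, 738 for CDKN1A and 618 for IL1RN. Without replicate 1 these genes had no untreated read and were at least 918-fold, 420-fold, 236-fold and 197-fold higher, ROR1-AS1 had a ratio of 658, and IL7R, XIRP1, ZNF365 and KCNN4 were at least 144-fold, 61.9-fold, 45.6-fold and 14.1-fold higher.

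Among the genes that fell most, PRTN3, the granule protease 3 of neutrophils, went from 37.3 ± 23.2 CPM to no read, at least 164-fold lower (77.4-fold without replicate 1 of wildtype PMA). On the log2 scale, IGLL1, a surrogate light chain of early B cells, changed by −7.18 ± 1.18, SELPLG, the ligand of P-selectin, by −5.02, NTHL1, a DNA glycosylase, by −4.63, and SDC1, a cell-surface proteoglycan, by −4.26. CDCA7 changed by −4.25, SMIM10 by −4.22, CDCA7L by −4.12, GINS2, a subunit of the replicative helicase, by −4.08, and SLC29A1, a nucleoside transporter, by −3.92.

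Among groups that rose in wildtype cells, adhesion and cytoskeleton had 14 of 26 tested members higher and none lower (18 higher when adjusted over the list alone; adjusted p = 1.58e-17, camera; adjusted p = 0.0503 with an estimated correlation). They included TIMP1, an inhibitor of metalloproteases, at 4.77 ± 0.41, ANXA2 at 5.52, the filament protein VIM at 2.93 and the adhesion receptor ICAM1 at 6.19. NF-kappaB targets had 13 of 19 higher (13 adjusted over the list alone; adjusted p = 2.07e-15; adjusted p = 0.0661 with an estimated correlation), such as TRAF1 at 4.79 ± 0.36, NFKB2 at 3.23 and BCL2A1, which protects from apoptosis, at 6.05. Immediate early and EGR family genes had 9 of 21 higher (10 adjusted over the list alone; adjusted p = 2.4e-09; adjusted p = 0.149 with an estimated correlation): the phosphatase DUSP6 rose by 3.75 ± 0.31, EGR2 by 5.69, EGR3 by 3.62 and SPRY2, a brake on growth factor signalling, by 2.78. Interferon response genes had 11 of 20 higher (13 adjusted over the list alone; adjusted p = 1.73e-09; adjusted p = 0.15 with an estimated correlation), among them OAS3 at 2.84 ± 0.49, OAS1 at 4.21 and IFI6 at 3.21. Of the inflammatory cytokines and chemokines 4 of 7 rose (6 adjusted over the list alone; adjusted p = 2.18e-08; adjusted p = 0.0661 with an estimated correlation), with the neutrophil attractant CXCL8 at 4.73 ± 0.8 and CXCL10, attracting T cells, at least 50.4-fold higher (24.6-fold without replicate 1 of the untreated wildtype). Their median of 4.73 was 4.69 with genes at 0 set to their bound.

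Phagocyte NADPH oxidase and receptors had 6 of 14 higher (10 adjusted over the list alone; adjusted p = 8.5e-07; adjusted p = 0.0661 with an estimated correlation), including the adaptor TYROBP at 2.26 ± 0.36 and RAC2 at 2.96. Macrophage markers had 3 higher and 1 lower of 12 (4 and 2 adjusted over the list alone; adjusted p = 7.28e-05; adjusted p = 0.155 with an estimated correlation): NRP1 rose by 6.10 ± 0.47 and SPP1, osteopontin, by 6.97, beside MMP9. Monocyte markers had 4 of 11 higher (4 adjusted over the list alone; adjusted p = 0.00372; adjusted p = 0.248 with an estimated correlation), the integrins ITGAX at 6.51 ± 0.7 and ITGAM at 5.67 and the calcium-binding S100A9 at 3.62 among them. CSF1R ligands and downstream signalling had 6 of 20 higher (6 adjusted over the list alone; adjusted p = 0.00171; adjusted p = 0.105 with an estimated correlation), with the Src-family kinase FGR at 6.15 ± 0.62. Genes of p53 and growth arrest had 4 higher and 1 lower of 18 (6 and 1 adjusted over the list alone; adjusted p = 0.00908; adjusted p = 0.15 with an estimated correlation), with BBC3 at 2.87 ± 0.6 and the cyclin CCND2 at −3.37. The protein kinase C family list, which also holds RASGRP and MARCKS genes, had 2 of 13 higher (4 adjusted over the list alone, adjusted p = 0.0301 by camera, adjusted p = 0.155 with an estimated correlation). These were RASGRP3 at 4.0 ± 0.72 and PRKCB at 1.99, of which only PRKCB encodes a protein kinase C. Lysosome had 2 of 25 higher (2 adjusted over the list alone, adjusted p = 0.0371 by camera, adjusted p = 0.462 with an estimated correlation), SCARB2 at 1.57 ± 0.33 and CTSH at 5.27.

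Ribosome biogenesis and MYC targets fell in wildtype cells, 17 of 22 lower (19 adjusted over the list alone; adjusted p = 6.85e-13, camera; adjusted p = 0.0661 with an estimated correlation), such as the nucleolar NOP56 at −1.90 ± 0.3 and NOLC1 at −1.67 and the pyrimidine enzyme CAD at −2.23. Cell cycle genes had 11 of 32 lower (11 adjusted over the list alone; adjusted p = 7.12e-08; adjusted p = 0.155 with an estimated correlation), among them the helicase subunits MCM4 at −2.78 ± 0.3, MCM6 at −2.22 and MCM7 at −2.17 and the transcription factor E2F1 at −2.60. Neutrophil granule and promyelocyte genes had 6 lower and 1 higher of 17 (6 and 1 adjusted over the list alone; adjusted p = 0.000184; adjusted p = 0.248 with an estimated correlation), with MS4A3 at −4.77 ± 0.91 and the growth factor HGF at 2.41 ± 0.5. Oxidative phosphorylation had 2 of 18 lower (2 adjusted over the list alone; adjusted p = 0.0202; adjusted p = 0.608 with an estimated correlation), NDUFV1 at −1.15 ± 0.29 and CYCS at −0.98 ± 0.27. None of the 16 lists that passed in wildtype cells held with an estimated correlation.

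In all, 799 genes rose and 767 fell with PMA in wildtype cells at an adjusted p under 0.05 (edgeR quasi-likelihood test, 13744 genes). The replicate block called 1515 and 1571, and fits of only the compared groups 1297 and 1145. Leaving out replicate 1 or 2 of the untreated wildtype left 428 or 392 higher and 366 or 347 lower, and leaving out replicate 1 or 2 of wildtype PMA left 497 or 506 higher and 227 or 311 lower. Of the 74 genes that the rule named and the test called, 55 stayed called without any 1 of the 8 libraries, and 19 did not. Without replicate 1 of the untreated wildtype, adjusted p was 0.0767 for HGF, 0.083 for S100A9, 0.107 for SCARB2, 0.0549 for CTSH, 0.149 for NDUFV1 and 0.15 for CYCS (edgeR). Without its replicate 2 it was 0.0609 for S100A9, 0.0728 for MS4A3, 0.0917 for PRKCB, 0.0856 for NDUFV1 and 0.189 for CYCS. Without replicate 1 of wildtype PMA it was 0.0511 for MS4A3, 0.0502 for PRKCB, 0.0996 for SCARB2, 0.314 for NDUFV1 and 0.208 for CYCS. Without its replicate 2 it was 0.182 for HGF, 0.0663 for S100A9, 0.065 for CTSH, 0.0928 for NDUFV1 and 0.354 for CYCS. CYCS was also lost without replicate 1 (0.0557) or 2 (0.0552) of mutant PMA.

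Of the lists in wildtype cells, lysosome did not pass without replicate 2 of the untreated wildtype (adjusted p = 0.218, camera) or replicate 1 of wildtype PMA (0.0591), and oxidative phosphorylation without replicate 1 of the untreated wildtype (0.222). The protein kinase C family did not pass without replicate 1 (0.0662) or 2 (0.0543) of the untreated wildtype or replicate 1 of wildtype PMA (0.083). With genes at 0 at their bound its median was 0.75, in place of 0.84.

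Lists that did not pass in wildtype cells were cholesterol biosynthesis (adjusted p = 0.686, camera), cohesin and chromatin architecture (0.602), CSF1R locus neighbours (0.962), dissociation and heat stress (0.388), glycolysis and hypoxia (0.843), lipid efflux and LXR (0.49), and markers of erythroid cells (0.943), B cells (0.901), T and NK cells (0.117), and platelets and megakaryocytes (0.0946). Mature neutrophil markers and regulators of CSF1R transcription both stood at adjusted p = 0.0808 and passed with the replicate block (0.0367 and 0.0459; adjusted p = 0.248 and 0.302 with an estimated correlation). Among regulators of CSF1R transcription 2 of 11 rose, EGR1 and EGR2.

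**Figure D2:**
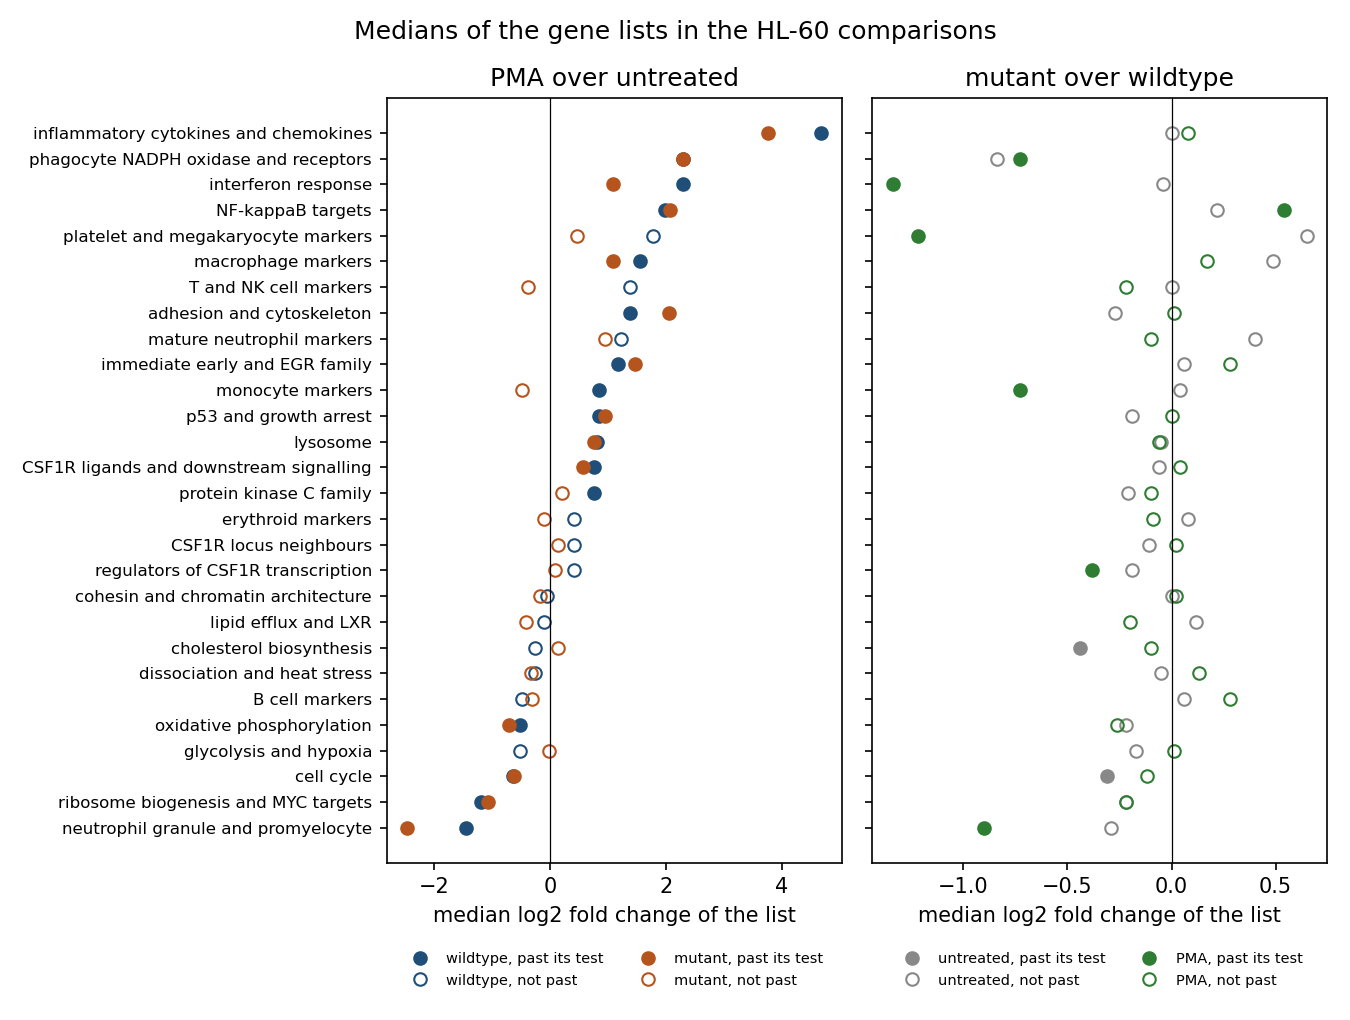
Median log2 fold change of 28 gene lists (horizontal axis), genes at 0 in a group set to their bound, for PMA over untreated cells in each line (left) and mutant over wildtype cells in each treatment (right). Filled points passed camera at an adjusted p under 0.05. The interferon response stood at −1.35 in mutant over wildtype cells after PMA.

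The mutant comparison asked the same of the edited line. In mutant cells 988 genes rose and 716 fell with PMA (edgeR, adjusted p under 0.05). MMP9 was at least 1440-fold higher, XIRP1 at least 282-fold, and MB rose by 9.48 ± 0.78 on the log2 scale, to 197 ± 124 CPM. Among other genes that rose were PHLDA1 (8.49 ± 0.52), SPP1 (8.04 ± 0.8), and RGS1, a regulator of G-protein signalling (8.27 ± 0.58). The antisense RNA ITGB2-AS1 had a ratio of counts of 1120 (200 to 44200), RGS13 one of 585 (104 to 23100), TNFAIP8L3 one of 506 (90.4 to 20000), and KCNN4 one of 215 (59 to 1780). Without replicate 1 of the untreated mutant the ratios of ITGB2-AS1, RGS13 and TNFAIP8L3 were 442, 231 and 200, and XIRP1 was at least 111-fold higher. Without replicate 2 of mutant PMA, MMP9 was at least 385-fold higher and KCNN4 53.8-fold (14.2 to 456). PROK2, a secreted attractant, went from 22.2 ± 1.09 CPM to no read, at least 93.4-fold lower (39.1-fold without replicate 1 of mutant PMA). PPP1R27 changed by −6.31 ± 0.42, IGLL1 by −6.04, PRTN3 by −6.43, SLC29A1 by −4.95, the receptor tyrosine kinase RET by −4.85, PLAC8 by −4.80, SDC1 by −4.80 and SMIM10 by −4.56. SELPLG had 87.3 times fewer reads (29.6 to 426), or 36.5 times without replicate 1 of mutant PMA.

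By group, adhesion and cytoskeleton had 17 of 26 members higher in the mutant with PMA (22 higher and 1 lower adjusted over the list alone; adjusted p = 1.51e-22, camera; adjusted p = 0.0456 with an estimated correlation), with TIMP1 at 5.46 ± 0.43, ANXA2 at 5.64 and S100A6 at 3.71. NF-kappaB targets had 14 of 19 higher (16 adjusted over the list alone; adjusted p = 1.57e-15; adjusted p = 0.0715 with an estimated correlation), with TRAF1 at 6.0 ± 0.37, ICAM1 at 5.63, the urokinase receptor PLAUR at 4.29 and BCL3 at 4.75. Immediate early and EGR family genes had 10 of 21 higher (12 adjusted over the list alone; adjusted p = 6.95e-11; adjusted p = 0.13 with an estimated correlation), with DUSP6 at 4.09 ± 0.31 and DUSP5 at 4.94. Phagocyte NADPH oxidase and receptors had 5 of 14 higher (9 adjusted over the list alone; adjusted p = 3.24e-05; adjusted p = 0.0715 with an estimated correlation), with TYROBP at 3.55 ± 0.38. Inflammatory cytokines and chemokines had 4 of 7 higher (6 adjusted over the list alone; adjusted p = 4.02e-06; adjusted p = 0.0715 with an estimated correlation), with IL1RN at 6.11 ± 0.53 and CXCL8 at 3.77; their median of 3.90 was 3.77 with genes at 0 at their bound. CSF1R ligands and downstream signalling had 7 of 20 higher (8 and 1 lower adjusted over the list alone; adjusted p = 0.00061; adjusted p = 0.0715 with an estimated correlation), with FGR at 6.84 ± 0.62 and SPRED1 at 3.44. Macrophage markers had 4 higher and 1 lower of 12 (5 and 1 adjusted over the list alone; adjusted p = 0.000808; adjusted p = 0.278 with an estimated correlation), with NRP1 at 5.66 ± 0.46. Interferon response genes had 6 of 20 higher (9 adjusted over the list alone; adjusted p = 0.00109; adjusted p = 0.361 with an estimated correlation), with IFI6 at 3.66 ± 0.58. Lysosome genes had 6 of 25 higher (8 adjusted over the list alone; adjusted p = 0.00988; adjusted p = 0.45 with an estimated correlation), with CTSB, a lysosomal protease, at 1.5 ± 0.29. Genes of p53 and growth arrest had 6 higher and 1 lower of 18 (7 and 1 adjusted over the list alone; adjusted p = 0.013; adjusted p = 0.203 with an estimated correlation), with CDKN1A at 6.17 ± 0.57 and BTG1 at 3.0.

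Ribosome biogenesis and MYC targets fell in the mutant as well, 13 of 22 lower (19 adjusted over the list alone; adjusted p = 8.34e-11, camera; adjusted p = 0.0715 with an estimated correlation), with NOP16 at −2.39 ± 0.37. Neutrophil granule and promyelocyte genes had 9 of 17 lower (13 adjusted over the list alone; adjusted p = 4.55e-08; adjusted p = 0.186 with an estimated correlation), with the granule enzyme MPO at −3.57 ± 0.62, NUCB2 at −2.16, and SERPINB10 at least 70.1-fold lower, or 13.3-fold without replicate 1 of the untreated mutant, which held 234 of its 253 reads. Cell cycle genes had 11 of 32 lower (11 adjusted over the list alone; adjusted p = 1.16e-05; adjusted p = 0.271 with an estimated correlation), with MCM4 at −2.08 ± 0.29. Oxidative phosphorylation genes stood lower as a list (adjusted p = 0.0115; adjusted p = 0.696 with an estimated correlation) with none of 18 members called over all genes or adjusted over the list alone. Of these 14 lists only adhesion and cytoskeleton held with an estimated correlation. Monocyte markers, with 3 of 11 higher and a median of −0.48, and the protein kinase C family had passed in wildtype cells and did not in the mutant (adjusted p = 0.394 and 0.17, camera). The other 12 lists that did not pass were the same as in wildtype cells, from adjusted p = 0.128 to 0.998. Without replicate 1 of the untreated mutant, 628 genes were higher, and p53 and growth arrest (adjusted p = 0.0757, camera) and oxidative phosphorylation (0.451) did not pass. Oxidative phosphorylation was at 0.25 and lysosome at 0.077 without replicate 2 and replicate 1 of mutant PMA, and macrophage markers at 0.257 without replicate 2 of the untreated mutant. Genes called lower numbered 352 without replicate 1 and 455 without replicate 2 of mutant PMA. The replicate block called 1764 higher and 1551 lower genes, DESeq2 1287 and 1080, and fits of only the compared groups 572 and 374. Of 68 named and called genes, 60 stayed called without any 1 of the libraries.

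Across genes, both PMA responses had a major-axis slope of 0.997 (mutant on wildtype, Pearson r = 0.64, Spearman rho = 0.636, 13744 genes), a description without a test, since genes are not replicates. At a mean of at least 10 CPM, a limit chosen after the data were seen, the slope was 1.038 and r 0.897 over 8458 genes. The slope was 1.772 without replicate 2 and 2.079 without replicate 1 of mutant PMA, 1.892 without replicate 2 of the untreated mutant, and 1.663 with no low-count filter. Pearson r in these fits was 0.371, 0.313, 0.311 and 0.186, over larger gene sets (15677 to 26548 genes), so their slopes are less certain. Genes called in both lines numbered 1138, and none of them had opposite directions. Of these 621 rose in both, against 57.4 for independent lists, and 517 fell in both, against 40.0. The 2 responses share no library, but both come from the same fit and its estimate of each gene's spread, so their calls are not independent. Of 1566 genes called in wildtype cells, 1552 had the same sign in the mutant.

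**Figure D3:**
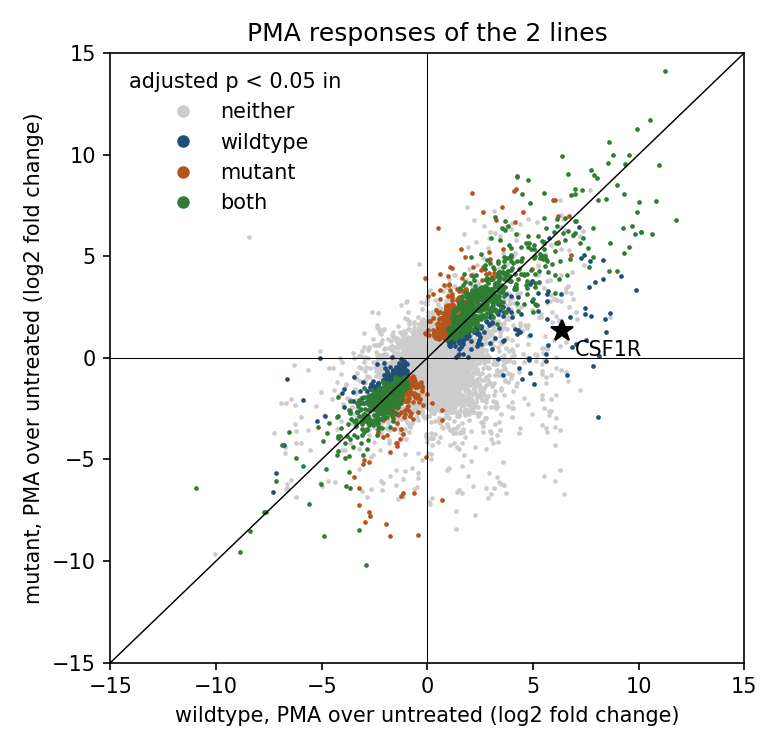
Log2 fold change with PMA in wildtype cells (horizontal axis) and mutant cells (vertical axis) for 13744 genes, coloured by the line in which edgeR called them; the diagonal marks equal responses. The star is CSF1R, at 6.39 and 1.34.

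A gene-by-gene test of the difference between both PMA responses called 0 genes (edgeR; 385 at an unadjusted p under 0.05; DESeq2 called 1 higher and 0 lower, and edgeR with no low-count filter 16 and 35). For lists, the interferon response gained less in the mutant (median difference −0.84, adjusted p = 0.000116, camera; adjusted p = 0.542 with an estimated correlation). Its members IFIT3 and MX2 had differences of −1.18 ± 0.77 and −2.76 ± 1.19, and none of the 20 passed, over all genes or adjusted over the list alone. Its call was lost without replicate 1 of wildtype PMA (adjusted p = 0.107), without replicate 2 of the untreated mutant (0.131) and without replicate 1 of mutant PMA (0.0534). The closing part gives the other 5 lists whose responses differed.

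Untreated mutant and wildtype cells were compared to find differences at baseline. Called genes numbered 0 (edgeR), with 852 at an unadjusted p under 0.05; DESeq2 called 25 higher and 42 lower, and the replicate block 22 and 47, of which 16 and 30 were shared. In the blocked fit CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, was 538 ± 182 CPM in wildtype and 2.04 ± 1.82 in mutant cells (−8.48 ± 0.68, adjusted p = 8.94e-05, edgeR with block). CST7, a cysteine protease inhibitor, stood at −3.31 ± 0.38, ALOX5AP, needed for leukotriene synthesis, at −2.48, CPNE1 at −2.39 and the granule protease PRSS57 at −2.18. ACTL8, an actin-like gene, was higher in the mutant, 668 ± 183 against 93.3 ± 49.4 CPM (3.0 ± 0.37, adjusted p = 0.00297), as were ADM2 (3.90 ± 0.43), GAS7 (2.40), STC2 (2.06) and CBS (1.74). TFPI, an inhibitor of coagulation, was at least 25.1-fold higher, and CDKN1A had a ratio of 32.9 (5.53 to 1340). Without replicate 1 of the untreated wildtype both were bounds, at least 12.3-fold and 5.36-fold. CRIM1, PPP1R16B, TCEA2, IFI6 and TRAF3IP3 were lower in that fit (−2.90 to −1.97), and PHLDA2, MAML2 and TMTC1 higher (1.67 to 2.40). DESeq2 did not call CDKN1A (adjusted p = 0.124), CBS (0.099) or PHLDA2 (0.0531). In the fit without the block, the smallest adjusted p among these was 0.0707 (CPNE1, edgeR).

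As lists, cell cycle (median −0.31, adjusted p = 0.00547, camera; adjusted p = 0.883 with an estimated correlation) and cholesterol biosynthesis (median −0.44, adjusted p = 0.0277, camera; adjusted p = 0.883 with an estimated correlation) were lower in untreated mutant cells, with no member called over all genes or adjusted over the list alone. PCNA, the replication clamp, had a difference of −1.30 ± 0.42 and HMGCS1, of the sterol pathway, −0.78 ± 0.3. Both list calls were lost without replicate 1 of the untreated wildtype (adjusted p = 0.0776 and 0.158) and without replicate 1 of the untreated mutant (0.266 and 0.199). The block added adhesion and cytoskeleton (0.0369) and ribosome biogenesis and MYC targets (0.0419), both from 0.0551 (adjusted p = 0.883 with an estimated correlation for both). Over the list alone, CDKN1A (ratio of counts 32.9, 5.53 to 1340) and SESN2, a stress-induced regulator (log2 difference 1.38 ± 0.37), were higher among the p53 genes. That list did not pass (median −0.19, adjusted p = 0.998, camera). Calls over the list alone were also made among phagocyte genes (1 higher, 2 lower), monocyte markers (1 higher, 1 lower), inflammatory cytokines (1 higher), lysosome (1 lower) and neutrophil granule genes (1 lower). None of these lists passed. CSF1R locus neighbours did not pass (adjusted p = 0.998), nor did any of their 15 tested members.

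After PMA, mutant and wildtype cells were compared to find what the edited line lacks in the induced state. Interferon response genes were lower in the mutant as a list, with a median log2 difference of −1.35 and 19 of 20 members below 0 (adjusted p = 1.53e-09, camera; adjusted p = 0.416 with an estimated correlation). Adjusted over the list alone, 7 were lower and 0 higher, against 0 over all genes, among them ISG15 at −1.38 ± 0.4, IFIT1 at −2.99 ± 0.93, MX2 at −2.62, IFI6 at −1.69, OAS1 at −2.07 and RIGI, a sensor of viral RNA, at −1.31. IFI6 stood at 496 ± 338 CPM in wildtype and 153 ± 2.76 in mutant PMA cells, with 735 and 257 against 155 and 151 by library. It was lower in untreated mutant cells too, 12.1 ± 0.789 against 53.7 ± 36.8 CPM, and its log2 response to PMA given above was not smaller in the mutant. Within runs the list median was −1.72 in replicate 1 and −0.62 in replicate 2. Neutrophil granule and promyelocyte genes were lower too (median −0.90, adjusted p = 3.2e-06, camera; adjusted p = 0.416 with an estimated correlation), 7 lower and 1 higher adjusted over the list alone. These included HGF at −2.93 ± 0.52, the transcription factors CEBPE at −1.53 and MYB at −2.08, and RNASE2, an eosinophil ribonuclease, at −2.03, while PRTN3 was the higher one.

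Other lists lower in the mutant after PMA were monocyte markers (median −0.73, adjusted p = 0.00678, camera), with 2 lower adjusted over the list alone, among them S100A9 at −3.16 ± 0.81, phagocyte NADPH oxidase and receptors (−0.73, adjusted p = 0.0123) with none, regulators of CSF1R transcription (−0.38, adjusted p = 0.0143) with CEBPE and MYB, and platelet and megakaryocyte markers (−1.22, adjusted p = 0.0391) with the erythroid and megakaryocyte factor NFE2 at −2.66 ± 0.65. NF-kappaB targets were higher (0.54, adjusted p = 0.0375) with TRAF1 at 1.70 ± 0.29. With an estimated correlation these stood at adjusted p = 0.473 with an estimated correlation for monocyte markers, 0.805 for NF-kappaB targets and 0.416 for the other 3. Without replicate 2 of wildtype PMA the lists other than interferon response and NF-kappaB targets did not pass: neutrophil granule and promyelocyte 0.076, monocyte markers 0.143, phagocyte genes 0.0682, regulators 0.21, platelet markers 0.076. NF-kappaB targets were at 0.097 without replicate 1 of wildtype PMA and 0.494 without replicate 1 of mutant PMA, platelet markers at 0.0975 without that library, and regulators at 0.224 without replicate 2 of mutant PMA. The block added oxidative phosphorylation (0.0409, from 0.106; adjusted p = 0.967 with an estimated correlation). CSF1R locus neighbours did not pass (adjusted p = 0.961, median 0.02).

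Gene by gene, the contrast after PMA called 0 genes (edgeR), with 1063 at an unadjusted p under 0.05. DESeq2 called 55 higher and 84 lower, and the replicate block 73 and 96, of which 53 and 74 were shared. In the blocked fit FAM30A, a long non-coding RNA, was at least 230-fold lower in the mutant, 59.7 ± 19.2 CPM in wildtype PMA cells against no read. CLC reads were 1680 times fewer (301 to 66400), and 268 times fewer (47.4 to 10600) without replicate 2 of wildtype PMA, which held 1773 of the 1936 wildtype reads. PROK2 reads were at least 13.3-fold fewer. Without replicate 1 of mutant PMA these bounds were 96.2-fold for FAM30A and 5.57-fold for PROK2. ACSM3, a mitochondrial acyl-CoA synthetase, was lower (−3.44 ± 0.49), as were the complement receptor CR1 and CST7 (each −2.91) and RASGRP2, which activates the GTPase RAP1 (−2.85). SLC45A3 and RBM38 were lower in the blocked fit (−3.96 and −2.99) but not in DESeq2 (adjusted p = 0.487 and 0.407). TFPI was higher in the mutant by 5.61 ± 0.72, ACTL8 by 3.94 ± 0.4, MACC1 by 3.15, ADM2 by 3.07, BLVRB, a biliverdin reductase, by 2.53, PHLDA2 by 2.47, PDE3A and EMP1 by 2.30, and JDP2 by 2.26. SGK1, a serum-induced kinase, was higher by 2.23 in that fit, though not in DESeq2 (adjusted p = 0.624). In the blocked fit 10 genes were higher and 20 lower in the mutant in both treatments, against 0.1 and 0.3 for independent lists. These 2 contrasts share no library, but both come from the same fit and its estimate of each gene's spread, so their calls are not independent.

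Leaving out 1 library gave 2 to 36 genes lower and 0 to 26 higher in the mutant after PMA. Both highest counts came without replicate 2 of the untreated mutant. In untreated cells the counts were 0 to 6 in each direction, both highest without replicate 2 of wildtype PMA. With no low-count filter edgeR called 87 higher and 140 lower after PMA, and 64 and 82 in untreated cells.

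Macrophage and monocyte libraries were compared as single libraries, with no replicate check. FTL, the ferritin light chain, was 37.6-fold higher in the macrophage library (28.9 to 49.8; 1987 against 57 counts), CSTB, a cathepsin inhibitor, 21.2-fold (14.6 to 32), SPP1 10.8-fold (8.24 to 14.4), VIM 6.59-fold, ACTB 6.21-fold and CTSB 5.82-fold (5.04 to 6.75). GPNMB, a glycoprotein of macrophages, was 3.80-fold higher, TPP1, a lysosomal peptidase, and TGOLN2 4.51-fold, B2M 4.47-fold, KCTD12 5.89-fold, CD164 3.90-fold, LAPTM5 3.57-fold, the invariant chain CD74 3.62-fold and the mitochondrial MT-CO3 3.56-fold. Monocyte counts of CSTB, SPP1 and CTSB lay at 0.818, 0.828 and 0.911 times what their length alone gives, and those of ACTB, GPNMB, TGOLN2, KCTD12, CD164, LAPTM5 and CD74 at 1.17 to 1.94 times, so these ratios are wholly or partly against background reads. In the monocyte library THBS1, thrombospondin 1, was 4.57-fold higher (3.80 to 5.54) and NAMPT 1.93-fold (1.76 to 2.12). EREG, an EGF family ligand, was 1.67-fold higher there (1.40 to 1.99), and the mitochondrial MT-ND3 1.57-fold and MT-RNR2 1.55-fold. Macrophage counts of THBS1 and EREG lay at 0.901 and 1.04 times the length expectation, and the monocyte count of EREG at 1.72 times. LMF1, SHANK3, SHANK1 and SBNO2, with ratios of 1.67-fold to 1.75-fold towards monocytes, had fewer reads than the length expectation in both libraries. At least 4-fold differences at a mean of 1 CPM were seen in 25 genes towards the macrophage and 1 towards the monocyte, of 28467.

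CSF1R had 601 counts in the monocyte library (41.6 CPM, 38.3 to 45.0) and 498 in the macrophage library (37.1 CPM, 33.9 to 40.5), a ratio of 0.893 (0.791 to 1.01). These are 1.11 and 1.00 times the count that its length alone gives. In both libraries counts followed gene length. Reads per kilobase had a median of 9.01 in the monocyte and 8.27 in the macrophage library. This was taken over 13970 autosomal protein-coding genes of at least 10 kb. Most lay between 4.36 and 10.7, and between 3.50 and 10.5. Only 12 and 115 of these genes had at least 2 times the count expected from length. Shorter genes such as FTL, of 1578 bases, are not among them. Of all 28467 genes at a mean of at least 1 CPM, 581 reached 2 times in either library. Levels of most genes in these libraries, CSF1R among them, therefore cannot be read as RNA levels. Genes that stand well above the length expectation, such as FTL at 4.01 and 152 times, can be compared as counts on their assigned strand only. Of the small genes opposite a protein-coding gene at least 2 times over its expectation, 4 of 5 (monocyte) and 8 of 10 (macrophage) were so themselves, against 2.84% and 4.35% of those opposite other genes. Which share of the RNA of such a gene was counted on its own strand is not known. EGR1 had 49 and 78 counts, a ratio of 1.71 (1.18 to 2.5), at 1.42 and 2.46 times its expectation.

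**Figure D4:**
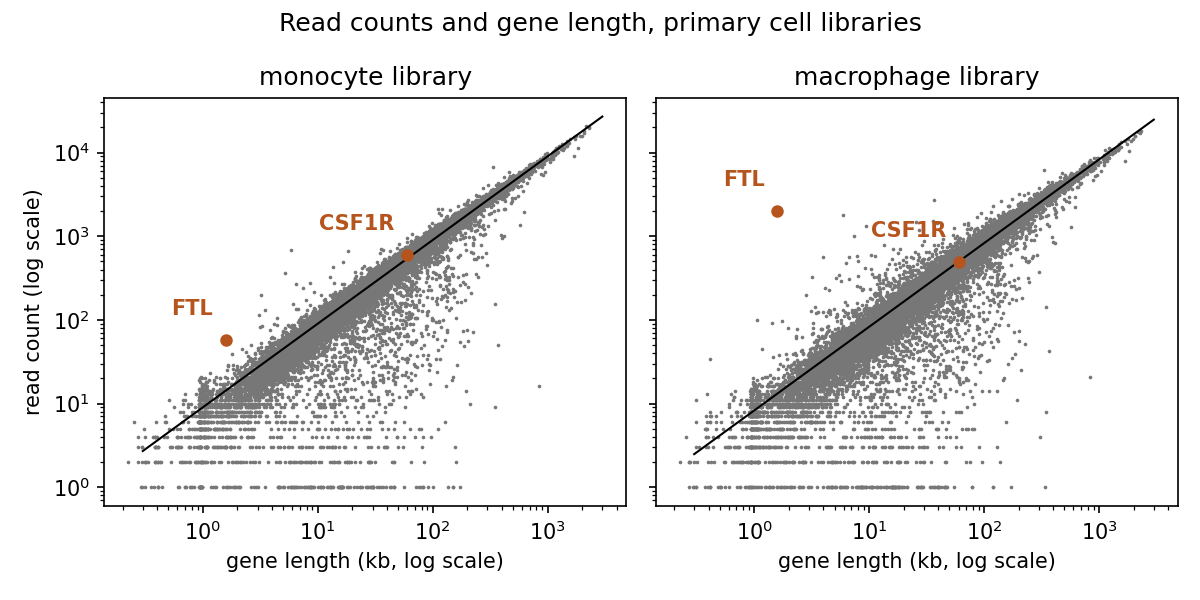
Read count (vertical axis, log scale) against gene length in kilobases (horizontal axis, log scale) for autosomal protein-coding genes in the monocyte and macrophage libraries. The line is the median of 9.01 (monocyte) and 8.27 (macrophage) reads per kilobase, taken over genes of at least 10 kb. CSF1R lies on it and FTL above it.

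Among lists, lysosome genes stood towards the macrophage, with a median log2 ratio of 0.59 (percentile 100 of random lists, 8 of 28 members at least 2-fold higher), such as CTSZ at 3.67-fold and GRN, progranulin, at 3.69-fold. Macrophage markers had a median of 0.26 (percentile 100; 5 of 29), with ACP5, an acid phosphatase, at 4.14-fold. Inflammatory cytokines and chemokines stood at 0.47 (percentile 100), with CCL2 at 3.31-fold. Glycolysis and hypoxia was at 0.19 (percentile 100), with GAPDH at 6.30-fold and LDHA at 3.14-fold. MHC class II had a median of 1.48 over 4 measured members of 12 (percentile 100). These were HLA-DRA at 10.4-fold (4.51 to 29.5), CD74 at 3.62-fold, CTSS at 2.3-fold and CIITA at 0.915-fold (0.811 to 1.03). HLA-DRA, the only HLA gene among them, had 6 monocyte and 58 macrophage counts, 0.128 and 1.35 times the length expectation. The median therefore does not stand for class II genes as a whole. Monocyte markers stood at 0.17 (percentile 100), led by LYZ, lysozyme, at 2.84-fold. Cell cycle (0.15, percentile 100), adhesion and cytoskeleton (0.12, percentile 100), dissociation and heat stress (0.18, percentile 99.8), lipid efflux and LXR (0.12, percentile 99.6), regulators of CSF1R transcription (0.13, percentile 99.1) and oxidative phosphorylation (0.11, percentile 98.6) stood towards the macrophage too. Neutrophil granule genes were at −0.14 (percentile 1.8) and CSF1R locus neighbours at −0.09 (percentile 2.0). The random lists were matched on mean CPM, which followed gene length here, and not on position. Locus neighbours lie close together on chromosome 5, and the granule genes AZU1, PRTN3, PRSS57 and CFD on chromosome 19. These 2 percentiles therefore cannot mark either list as unusual. Dendritic cell markers were at −0.03 (percentile 50.5), with CD1C at 0.704 times the monocyte level (0.481 to 1.02). Monocyte counts of CTSZ, GRN, ACP5, GAPDH and LDHA were 0.819, 0.554, 0.485, 0.973 and 0.83 times the length expectation, and that of CCL2 1.45 times. List medians in monocytes and macrophages were 1.02 and 1.53 times it for lysosome, 0.911 and 1.12 for macrophage markers, and 1.01 and 0.88 for neutrophil granule genes, so these list ratios mostly compare counts near the length level. In 95% of draws, random lists of the same size had medians between −0.08 and 0.06 for lysosome, the widest range being −0.20 to 0.18 for the 4 members of MHC class II.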

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

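The tests of reads on the opposite strand, of clumped reads in olfactory receptor genes, of RNA of another cell type, of a state of the untreated mutant, of a weaker response of the whole mutant and of the number of lines were chosen after the result was seen.

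The PMA response differed between the mutant and the wildtype line for 6 gene lists, by a test of the difference itself (camera). The difference, mutant minus wildtype, was negative for the interferon response (adjusted p = 0.000116, camera, median difference −0.84), monocyte markers (0.00358, −0.88), neutrophil granule and promyelocyte genes (0.00358, −0.74), mature neutrophil markers (0.00762, −0.84) and platelet and megakaryocyte markers (0.0189, −1.77). It was positive for adhesion and cytoskeleton genes (0.00762, 0.24). In the mutant itself the median with PMA was 1.08 for the interferon response, 0.95 for mature neutrophil and 0.46 for platelet markers. It was −0.48 for monocyte markers, −2.47 for neutrophil granule genes and 2.06 for adhesion and cytoskeleton. Single members called over all genes numbered 0 (edgeR; 385 of all genes at an unadjusted p under 0.05; DESeq2 called 1). Adjusted over the list alone, S100A6 (1.95 ± 0.44) passed among adhesion and cytoskeleton genes and PROK2 among mature neutrophil markers. With an estimated correlation none passed (adjusted p = 0.542 for 5 lists and 0.606 for neutrophil granule and promyelocyte genes, with an estimated correlation).

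Each of these 6 list results was lost without some single library. Adhesion and cytoskeleton stood at adjusted p = 0.0689 without replicate 1 of the untreated wildtype and 0.061 without replicate 2 of wildtype PMA. Monocyte markers were at 0.169 without replicate 2 of wildtype PMA and 0.136 without replicate 2 of the untreated mutant. Neutrophil granule and promyelocyte genes were at 0.156, 0.85, 0.481 and 0.0931 without replicate 1 of the untreated wildtype, replicate 2 of wildtype PMA, replicate 2 of the untreated mutant and replicate 2 of mutant PMA. Mature neutrophil markers were at 0.0531, 0.155, 0.136 and 0.0824 without replicate 1 of the untreated wildtype, replicate 2 of wildtype PMA, replicate 2 of the untreated mutant and replicate 1 of mutant PMA. Platelet and megakaryocyte markers passed only in the absence of replicate 1 of the untreated wildtype, and ranged from 0.0569 without replicate 1 of wildtype PMA to 0.277 without replicate 2 of the untreated wildtype. For the interferon response the values were 0.107 without replicate 1 of wildtype PMA, 0.131 without replicate 2 of the untreated mutant and 0.0534 without replicate 1 of mutant PMA.

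Interferon response genes stood lower in the mutant after PMA as a list by camera (adjusted p = 1.53e-09), but the call was lost with an estimated correlation (adjusted p = 0.416 with an estimated correlation) and by fry (0.263). A difference between the runs was tested within each run, where it cancels if both lines share it: the list median was −1.72 in the first and −0.62 in the second, below 0 in both. A weaker PMA response of the mutant as a whole was tested on the 788 other genes that rose with PMA in the wildtype, whose median difference was −0.03. What stays open is whether the edited enhancer, another difference of the mutant line or variation between single libraries lies behind it. The number of mutant lines was 1 and each run held 1 library per group, so these cannot be told apart. In untreated cells the within-run medians were −0.4 and 0.01.

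In the monocyte and macrophage libraries, reads per kilobase were alike across genes. Intron reads of transcribed genes and reads counted on the opposite strand both need RNA. Olfactory receptor genes are silent in blood cells, yet 312 (monocyte) and 313 (macrophage) of 373 had a read. Their median of reads per kilobase was 0.822 (monocyte) and 0.888 (macrophage) of that of protein-coding genes of at least 10 kb. Genomic DNA in the libraries needs that median to be near the others, and it was. Genomic DNA may thus account for most reads there. Reads of RNA may lie on the opposite strand as well. Where a protein-coding gene was at least 2 times over its length expectation, the small gene opposite it was so too in 4 of 5 pairs (monocyte) and 8 of 10 (macrophage), and had more reads per kilobase than that gene in 2 and 6. The small gene opposite LYZ had 532 reads per kilobase against 115 over the whole of LYZ in the monocyte library, and 1510 against 303 in the macrophage library. Such densities do not compare both strands over the same stretch, since that of the protein-coding gene includes its introns. The small genes may also have RNA of their own. Whether the strand setting of these files was inverted stays open. No biological explanation was tested.

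Replicate 1 of the untreated mutant had scattered reads in long genes that were silent or weakly expressed in the other HL-60 libraries. It had 7.25 reads per megabase in them (scaled to library totals) against 0.505 to 2.47 elsewhere. These genes, called long silent genes here, were protein-coding, over 500 kb and had a median below 1 CPM in the other libraries. They may hold some RNA reads, and the set differed by library (50 to 67 genes). A state of the untreated mutant cells was tested on replicate 2 of that group, which had 1.02 times the higher untreated wildtype library. Genomic DNA in the library stays open. Olfactory receptor reads were 0.85 of the highest other library, under the 2 times set beforehand, which by that prediction goes against genomic DNA. Only 10 of the 57 reads there lay in olfactory receptor genes without a read elsewhere. The ratio thus mostly compares genes with reads in other libraries too, and says little about scattered reads. OR2W3 was 1 of them, with 7 reads there and 12 to 27 in each other library. Of 338 olfactory receptor genes without a read elsewhere 3 had one. At the density of the long silent genes 25.1 would have one if reads fell singly, which goes against genomic DNA, and 7.53 (3 to 13) in clumps of 3.97, the mean in short silent genes with a read. RNA reads in the long genes would make both expectations too high. The clump size came from the same library, and RNA reads in the short genes would make it too large and the 7.53 too low. The count in clumps therefore cannot decide the question. RNA of another cell type stays open too. ALB had 0 reads beside 33 of PLG and SNAP25 0 beside 49 of ELAVL4, which goes against RNA of liver or nerve cells. For other cells, the highest of the 407 genes seen there alone reached 5.28 CPM. A prediction chosen after the result was seen asked for at least 50 CPM, and by it this value goes against such RNA. That bound was assumed and rests on no cell profile, so the question was left open once the value was seen.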

How the results depend on the processing

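Tests on protein-coding genes only, the slope at a mean of at least 10 CPM and genes above their length expectation were chosen after the result was seen. Of 185 named results other than those of CSF1R, 141 were called. The others were mostly genes between lines that were named because the blocked fit called them. Most additions by the block were therefore fixed by that choice. Additions under the other settings were counted on the same chosen genes. The replicate block lost 0 and added 41, size factors of the DESeq2 type lost 0 and added 0, no low-count filter lost 1 and added 41, DESeq2 lost 1 and added 35, and fits of only the compared groups lost 5 and added 5. Where a cause is not given below, the cause was not tested.

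With the replicate block, genes higher and lower with PMA numbered 1515 and 1571 in the wildtype and 1764 and 1551 in the mutant. Between lines the block gave 22 higher and 47 lower untreated and 73 and 96 after PMA, and 4 lists in untreated cells; apart from these, the named results and the list results given above, it changed no other call. At an adjusted p under 0.01 the PMA counts were 364 and 242 in the wildtype and 462 and 241 in the mutant, by construction fewer. Fits of only the compared groups gave 1297 higher in the wildtype, 572 and 374 in the mutant, 3 lower between untreated lines, and 3 higher and 3 lower after PMA. DESeq2 gave 1080 lower in the mutant with PMA, 25 and 42 between untreated lines, 55 and 84 after PMA, and 1 higher for the difference of responses. No low-count filter gave 64 and 82 between untreated lines, 87 and 140 after PMA, 16 and 35 for the difference of responses, −5.01 for CSF1R there, and a slope of 1.663.

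With an estimated correlation 0 lists passed in wildtype cells with PMA, 1 in the mutant, 0 in each contrast between lines and 0 for the difference of responses. Fry lost 22 of 45 list results: 0 passed in the last 3 contrasts, and with PMA it lost lysosome (0.106), monocyte markers (0.0683), neutrophil granule and promyelocyte (0.068) and oxidative phosphorylation (0.23) in the wildtype, and interferon response (0.0693), lysosome (0.0693) and oxidative phosphorylation (0.236) in the mutant. In the primary cells a prior of 0.25 CPM gave 38 genes at least 4-fold higher. CSF1R had no value between untreated lines in fits of only the compared groups, where it was filtered out.

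Leaving out 1 library, whose group was then assumed to vary like the others, gave these ranges. Genes with PMA: 392 (without untreated wildtype replicate 2) to 1012 higher and 227 to 946 lower in the wildtype, and 628 to 1018 higher and 352 to 641 lower in the mutant. Between lines: 0 to 6 higher and 0 to 6 lower untreated, 0 to 26 and 2 to 36 after PMA, and 0 to 2 and 0 to 1 for the difference of responses. CSF1R ranged from 5.40 to 9.66 with PMA in the wildtype, 0.30 to 7.67 in the mutant, −3.16 to 6.43 between untreated lines, −2.99 to −1.23 after PMA, and −8.30 to 1.28 for the difference of responses. The ends 9.66, 7.67, −3.16, 6.43, −8.30 and 1.28 come from fits in which the remaining untreated library had 0 CSF1R reads, and are neither folds nor bounds. EGR1 ranged from 1.26 to 2.62 in the wildtype, 1.26 to 2.58 in the mutant, −1.01 to 0.66 between untreated lines and −0.90 to 0.77 for the difference of responses. It reversed between untreated lines at 0.66 and 0.28, and for the difference at 0.50, 0.07, 0.77 and 0.21. The slope ranged from 0.818 to 2.079. Lists that passed numbered 14 to 19 and 13 to 14 with PMA, 1 to 11 between untreated lines, 3 to 7 after PMA and 1 to 11 for the difference of responses. Depth limits genes near a floor of 0.347 to 0.605 CPM.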

Other observations

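The test of long genes silent or weakly expressed in the other libraries was chosen after the result was seen. CSF1R had 28 reads in replicate 1 of the untreated mutant, while the reads of long silent genes there would give 3.76 over its length if they fell singly. The 407 genes seen there alone had a median of 1.4 and reached 5.28 CPM, so CSF1R at 3.02 CPM lay within their range. Whether its reads are background cannot be told.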
